A study of Mus musculus with 6 samples.

How the data were processed

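The samples are 6 total RNA preparations from mouse liver, 3 labelled Atp7b knockout and 3 labelled wild type, each hybridised to 1 Affymetrix array. Per the labels' protocols, RNA was extracted with TRIzol and cleaned on RNeasy columns, and labelled with an Enzo kit. The deposited values are intensity values on a linear scale. Per the labels, they are MAS 5.0 signals, and each array was scaled as a whole to a target average of 350; the submitters' processing notes name the same software. The table used here holds 11811 probe sets, fewer than the array type carries, and how they were chosen is not given in the sources used here. Their mean, trimmed by 2% at each end, was 719.1 to 729 per array, above that target. No detection calls were used. Array medians were within 3.63% of each other. MAS 5.0 subtracts mismatch signals and scales by 1 factor per array, so low signals are noisy and the shapes of the distributions were left as they were. Sequencing depth does not apply; the number of arrays limits the precision.

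Groups were taken from the sample titles. The sample numbers of the groups do not match, so samples were not paired. The labels name each sample after a mouse but give no sex, age, strain, diet or time of sampling, and nothing states outright that each sample is a separate animal, so p-values measure the spread between these samples. No pair of arrays held duplicate values (at most 0.0847% of values identical).

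The comparison was knockout against wild type on log2(signal + 16). Fold changes are on this scale, which understates the change of low signals. The 33 control probe sets were left out, as were 1158 with a mean signal under 100, which left 10620. A linear model was fitted with limma (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. No exact permutation test of a single gene in 3 against 3 samples can go below 0.1. The standard errors are limma's moderated ones.

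Probe sets were named from the platform annotation, with symbols updated through Entrez identifiers in a RefSeq gene table of mouse assembly GRCm38.p6, which was used only for names and for the order of neighbouring genes. Of 11778 probe sets other than controls, 10776 had 1 gene symbol, 418 several and 584 none. The identifiers of 10762 were found, and 0 symbols changed. Probe sets with several symbols were not named, and 45 of the called ones had no single symbol. Where a gene had several tested probe sets, the one with the highest mean signal stood for it (6604 genes).

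Before the data were examined, 27 gene lists and 12 cell-type marker lists were fixed, along with the rule for the genes named and all alternatives below. Named were Atp7b, Mt1 and Mt2; the 12 genes with the largest increase and the 12 with the largest decrease among called genes with a mean signal of at least 200 in the higher group and no overlap between groups, ranked on the probe set that stood for the gene; and up to 4 called members of each list with the smallest p, or, in a list called by camera with fewer than 2 called members, the 2 with the smallest p. This gave 77 genes, 71 of them called. Of these, 36 had other tested probe sets, and none of those had the opposite sign. Lists with at least 4 tested genes (32 lists) were tested with limma's camera at a preset correlation of 0.01, which asks whether a list lies higher or lower than other genes, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list called none (smallest adjusted p = 0.339; 2 at an unadjusted p under 0.05). Limma's fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, called 4: metallothioneins and zinc transporters, cytochrome P450 and conjugation, male-predominant genes, and cell cycle.

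The scripts were tested on simulated data built from the tested probe sets. With 200 of 10620 probe sets changed in 20 runs of 3 against 3, 31.5% of those changed by 0.5 on the log2 scale were recovered, 96% of those changed by 1 and 100% of those changed by 2, and 6.51% of calls were unchanged probe sets. Camera called 1 of 640 unshifted lists and found a list shifted by -0.5 in 20 of 20 runs; those simulated genes vary independently, which real genes of 1 list do not.

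Alternatives were quantile normalization, centring of each array on its median, a pseudocount of 1 or 64, no filter on signal, a minimum mean signal of 200, eBayes without the trend or robust, array weights, leaving out each sample, a threshold of 0.10, an estimated correlation, fry, and the mean over the probe sets of a gene. The list tests were not rerun under the robust setting, which camera does not take. The versions were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the figures.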

Results

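Total liver RNA was profiled on Affymetrix expression arrays, with 1 array per sample. Of the samples, 3 were labelled as liver of mice lacking Atp7b, the copper-transporting ATPase whose loss causes the copper storage disorder Wilson disease, and 3 as liver of wild-type mice. They are named here by genotype and by the number in their labels, as KO903, KO904 and KO905 (knockout) and WT4, WT5 and WT6 (wild type). The deposited table held scaled MAS 5.0 signals for 11811 probe sets, and 10620 of them, with a mean signal of at least 100 over the 6 arrays, were tested. Median signals lay between 330.8 and 342.8 on all arrays. Ratios of 3' to 5' signal were 1.1 (WT5) to 1.47 (WT6) for actin and 0.815 (KO903) to 0.99 (WT6) for Gapdh. Correlations of log2 signals were at least 0.974 between arrays of 1 group and at most 0.97 between arrays of different groups. The first principal component carried 43.2% of the variance and separated the groups. The second carried 18.8% and set WT5 (-19.8) and WT6 (14.7) apart, with the other arrays between -5.64 and 5.23. The comparison asks which liver transcripts differ without Atp7b, at a stage that the series title places early in copper accumulation.

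In the Atp7b knockout livers the metallothionein transcripts Mt1 and Mt2, which encode small metal-binding proteins, rose 2.20-fold and 2.86-fold. Transcripts of lipid synthesis fell: 8 of 18 tested genes of cholesterol biosynthesis and 7 of 20 of fatty acid and triglyceride synthesis passed the test as lower, and none of either list passed it as higher. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 3.66-fold. Among the largest single increases were Mad2l1, Cenpq, Pttg1 and Smc4 (2.88-fold to 5.35-fold), while 2 of 16 genes of the cell cycle list were called (camera adjusted p = 0.18, or 0.0224 at a minimum signal of 200). In all, 440 probe sets passed an adjusted p of 0.05 in limma, 218 higher and 222 lower in the knockout, and 123 of them changed at least 2-fold, 53 upward and 70 downward. The higher probe sets named 168 genes and the lower ones 159, and in all 440 the 3 knockout values lay apart from the 3 wild-type values. Such separation occurred in 23.6% of all tested probe sets, against 10% by chance for 3 against 3. The count varied with the samples kept: without KO903, KO904 or KO905 it was 193, 175 or 228, without WT4, WT5 or WT6 it was 254, 475 or 272, and with each array centred on its median 186 calls were upward and 267 downward.

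The targeted gene itself was measured by 1 probe set. Its signal was 219 ± 29.9 (SD, n = 3) in the knockout and 267 ± 30.1 (SD, n = 3) in wild type, a log2 difference of -0.27 ± 0.16 (SE) with an adjusted p of 0.407. The position of this probe set relative to the disrupted part of the gene was not examined, and a probe outside that part cannot check the genotype. The labels therefore stand unchecked by the array.

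Among the genes named for metallothioneins and zinc transporters, 3 of 10 tested rose and 1 fell, with the same counts adjusted over the list alone. Mt2 went from 7092 ± 1630 (SD, n = 3) in wild type to 20004 ± 1825 (SD, n = 3) in the knockout, a log2 difference of 1.52 ± 0.15 (SE; adjusted p = 0.000341). Mt1 went from 11968 ± 1989 to 26290 ± 3221 (SD, n = 3 each; log2 1.14 ± 0.13, adjusted p = 0.000747). The zinc and manganese importer genes moved apart: Slc39a14 fell (log2 -0.98 ± 0.12, adjusted p = 0.0018) and Slc39a8 rose (log2 0.52 ± 0.12, adjusted p = 0.0353). A second probe set of Slc39a14 did not pass (log2 -0.40, adjusted p = 0.236). As a list these genes lay higher than other genes in the camera test (adjusted p = 0.0274), and the call was lost with an estimated correlation (adjusted p = 0.339) and without KO903 (adjusted p = 0.0532). In the copper transport and chaperone list, Atox1, the chaperone that delivers copper to Atp7b, rose from 1609 ± 158 to 2315 ± 87.3 (SD, n = 3 each; log2 0.52 ± 0.11, adjusted p = 0.0251), the only call among 12 tested (3 higher adjusted over the list alone). That list was not shifted (adjusted p = 0.357), nor was iron handling, with no call by limma among 10 tested genes (2 at an unadjusted p under 0.05), 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.788). Leaving out 1 library ended the call of Atox1 for KO903, KO904, KO905 or WT6 (adjusted p up to 0.0972) and that of Slc39a8 for each of the 6 (up to 0.123).

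The largest increases, besides Mt2, were in Cyp2c39, Mad2l1, Selenoh, H1f2, Cenpq, Pttg1, Smc4, Abhd1, Lpl, Kdm2b and Cyp7b1. Mad2l1, a spindle checkpoint gene, went from 125 ± 51.2 to 707 ± 59.8 (SD, n = 3 each; log2 2.42 ± 0.23, adjusted p = 0.000266). Selenoh, a nuclear selenoprotein, rose from 229 to 1036 (log2 2.11 ± 0.15), the linker histone gene H1f2 from 625 to 2310 (log2 1.87 ± 0.14) and the histone demethylase gene Kdm2b from 130 to 349 (log2 1.33 ± 0.15). Lpl, which encodes lipoprotein lipase, rose from 1199 to 3127 (log2 1.44 ± 0.24). Abhd1 rose by a log2 difference of 1.45 ± 0.30. The cytochrome P450 gene Cyp2c39 stood at 5344 ± 301 in the knockout and 1093 ± 1385 in wild type (SD, n = 3 each; log2 3.07 ± 0.64, adjusted p = 0.0237). Its wild-type values were uneven, with 2693 in WT4 against 283 and 305 in WT5 and WT6, and without WT4 the log2 difference was 4.11. Without KO903, KO904, KO905 or WT6, the calls of Cyp2c39 and Abhd1 ended (adjusted p up to 0.0975 and 0.0854).

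The largest decreases were in Cyp2c37, Amacr, Adi1, Cyp7a1, Slc26a1, Idi1, Sqle, Fabp5, Thrsp, Hmgcs1, Esco1 and Lpin1. Cyp2c37, another cytochrome P450 gene, fell from 6045 ± 954 to 311 ± 36.2 (SD, n = 3 each), an 18.5-fold decrease (log2 -4.21 ± 0.14, adjusted p = 5.92e-08), read from 1 probe set, as for Cyp2c39. Amacr, a racemase of branched-chain fatty acid and bile acid oxidation, fell from 1949 ± 436 to 362 ± 66.1 (SD, n = 3 each; log2 -2.37 ± 0.18, adjusted p = 6.04e-05). The sulfate transporter gene Slc26a1 fell from 643 to 164 (log2 -1.87 ± 0.13), the fatty acid binding protein gene Fabp5 from 5581 to 1842 (log2 -1.70 ± 0.31) and the cohesin acetyltransferase gene Esco1 from 264 to 79.1 (log2 -1.56 ± 0.17). Adi1, of the methionine salvage pathway, fell on its brightest probe set (log2 -1.94) and on another (log2 -2.92), while its remaining tested probe set did not pass (log2 -0.14, adjusted p = 0.833).

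**Figure D1:**
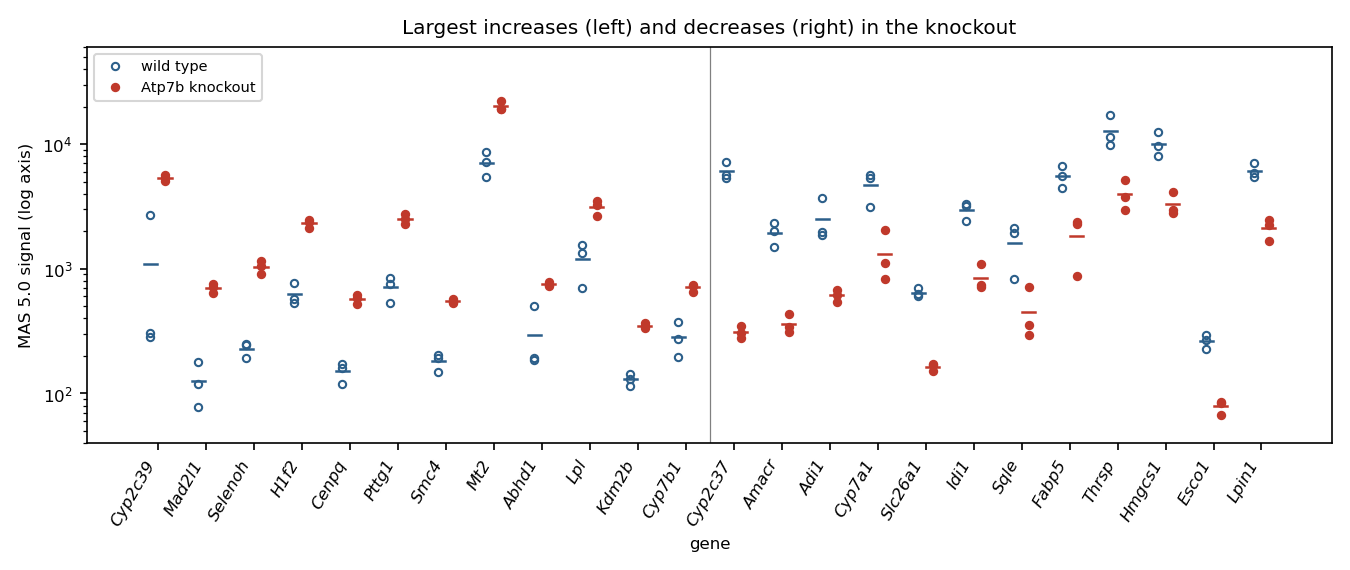
MAS 5.0 signal on a log axis for the 12 genes with the largest increase and the 12 with the largest decrease in the knockout, with 1 point per library (open, wild type; filled, Atp7b knockout; n = 3 each) and a bar at each group mean. Knockout and wild-type points do not overlap for any of the 24 genes, which the rule for choosing them required. For Cyp2c39 1 wild-type library lies at 2693, above the other wild-type points at 283 and 305.

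All 18 tested genes of cholesterol biosynthesis had lower mean log2 signals in the knockout, by a median of 0.67 (log2 -0.67), and 8 of them passed the threshold (16 adjusted over the list alone). Hmgcs1, the enzyme that makes HMG-CoA, went from 10018 ± 2207 to 3293 ± 733 (SD, n = 3 each; log2 -1.60 ± 0.17, adjusted p = 0.000713), and its other 3 probe sets fell too. Idi1, which isomerises isopentenyl diphosphate, fell from 2964 ± 482 to 847 ± 214 (SD, n = 3 each; log2 -1.80 ± 0.18, adjusted p = 0.000332). Later steps fell as well, with log2 differences of -1.04 ± 0.13 for Fdft1, -1.79 ± 0.35 for Sqle and -1.39 ± 0.25 for Cyp51. The list lay lower than other genes in camera (adjusted p = 1.5e-16), but not with an estimated correlation between its genes (adjusted p = 0.339). In the list of sterol sensing and cholesterol uptake, 2 of 13 genes fell (2 higher and 4 lower adjusted over the list alone): Stard4, a sterol carrier (log2 -0.97 ± 0.12, adjusted p = 0.00162), and Srebf1, which encodes the lipogenic transcription factor SREBP-1 (log2 -0.72 ± 0.15, adjusted p = 0.0235). That list was not shifted (adjusted p = 0.324), with a median of 0.05, from -0.06 without WT5 to 0.12 without WT6, and a mean of -0.07. Calls that ended with 1 library left out were Cyp51 without KO904 (adjusted p = 0.0609), Sqle without KO903, KO904 or WT4 (up to 0.0931) and Srebf1 without KO904, KO905 or WT4 (up to 0.106).

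Fatty acid and triglyceride synthesis showed the same direction. Of 20 tested genes 7 fell (11 adjusted over the list alone) and 2 had a log2 difference above 0, with a median of -0.48. Thrsp, a lipogenesis regulator, went from 12821 ± 3811 to 3945 ± 1100 (SD, n = 3 each; log2 -1.69 ± 0.22, adjusted p = 0.0018). The phosphatidate phosphatase genes Lpin1 and Lpin2 fell by 1.54 and 0.70 on the log2 scale, and Dgat2, which makes triglycerides, by 0.53. One further probe set of Lpin2 missed the threshold (adjusted p = 0.0549). Camera placed the list lower (adjusted p = 1.92e-11), again not with an estimated correlation (adjusted p = 0.339). Among 24 genes of fatty acid oxidation and PPARalpha targets, Ppara itself fell from 2668 ± 504 to 1230 ± 162 (SD, n = 3 each; log2 -1.10 ± 0.15, adjusted p = 0.00258) and the pantetheinase gene Vnn1 rose (log2 0.90 ± 0.19, adjusted p = 0.0233). The other 22 did not pass, the whole list had 1 higher and 3 lower adjusted over the list alone, and it was not shifted (adjusted p = 0.266). The call of Vnn1 ended without KO903 or KO905 (adjusted p up to 0.0914).

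**Figure D2:**
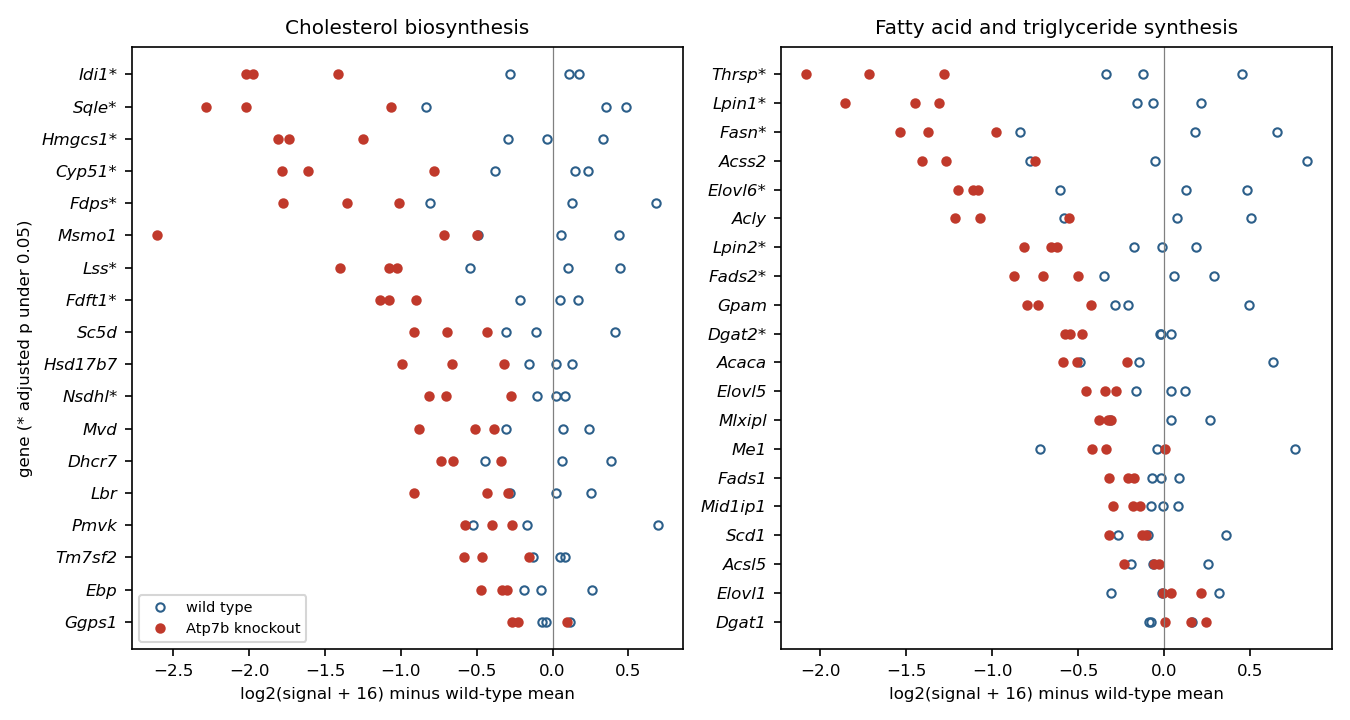
Log2(signal + 16) minus the wild-type mean, 1 point per library (open, wild type; filled, Atp7b knockout; n = 3 each), for the 18 tested genes of cholesterol biosynthesis and the 20 of fatty acid and triglyceride synthesis, with a star at adjusted p under 0.05. Points of the knockout lie left of 0 for most genes, and 8 and 7 genes passed the threshold.

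In bile acid synthesis and hepatobiliary transport, 4 of 22 tested genes fell and 1 rose (6 lower and 5 higher adjusted over the list alone). Cyp7a1 went from 4710 ± 1363 to 1325 ± 633 (SD, n = 3 each; log2 -1.87 ± 0.30, adjusted p = 0.00625). Cyp7b1, of the alternative pathway, rose from 281 ± 91.8 to 708 ± 48.5 (SD, n = 3 each; log2 1.33 ± 0.20, adjusted p = 0.00487). The bile acid uptake transporter gene Slc10a1 fell by 0.48 on the log2 scale (adjusted p = 0.013), a call that ended without KO904 or KO905 (adjusted p up to 0.0604). Camera placed the list lower (adjusted p = 0.0274), and the call was lost with an estimated correlation (adjusted p = 0.431). Leaving out KO905 (adjusted p = 0.0579), WT5 (0.0916) or WT6 (0.0794) also ended it, as did quantile normalization (0.0878), array weights (0.053) and eBayes without a trend (0.0506). Among 15 genes of lipoproteins and apolipoproteins, the phospholipid transfer protein gene Pltp fell (log2 -1.15 ± 0.18, adjusted p = 0.00545), Lpl rose (adjusted p = 0.00867) and 13 did not pass. The whole list had 2 higher and 1 lower adjusted over the list alone, and was not shifted (adjusted p = 0.788), with a median of -0.01 and a mean of 0.02. The sign of that median was not stable: it was -0.10 without WT4, and above 0 without KO905 (0.05) or WT5 (0.06), with array weights and after quantile normalization.

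Most tested genes of the cell cycle list were not called. In the list of cell cycle, DNA replication and mitosis, 16 of 50 genes were tested, Mad2l1 and Smc4 rose and 14 did not pass; the whole list had 3 higher and 1 lower adjusted over the list alone. Smc4, a condensin subunit, rose from 182 ± 30.5 to 549 ± 20 (SD, n = 3 each; log2 1.52 ± 0.15, adjusted p = 0.000332). Securin (Pttg1) and the centromere protein gene Cenpq, outside the list, rose by log2 differences of 1.82 ± 0.16 and 1.84 ± 0.16. In a family put together after the values were seen, 9 of 22 kinetochore, checkpoint and condensin genes were called higher and 0 lower. Camera did not place the list higher than other genes (adjusted p = 0.18), except at a minimum signal of 200 (adjusted p = 0.0224). Fry, which compares the list with no other genes, gave an adjusted p of 0.038 for a rise on balance. The p53 targets and DNA damage genes rose in 4 of 14 cases (5 adjusted over the list alone): Ccng1 by a log2 difference of 1.07 ± 0.15, Phlda3 by 1.05 ± 0.14, Brca1 by 1.07 ± 0.20 and Gadd45g by 0.71 ± 0.18. Camera placed this list higher (adjusted p = 0.0032), but not with an estimated correlation (adjusted p = 0.422). The call of Gadd45g (adjusted p = 0.0477) ended when any of the 6 libraries except WT5 was left out (up to 0.154).

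Genes of NRF2 targets and glutathione metabolism rose in 4 of 28 cases (9 higher and 1 lower adjusted over the list alone), and 24 of 28 log2 differences were above 0. Aox1, an aldehyde oxidase, went from 955 ± 56.6 to 1855 ± 194 (SD, n = 3 each; log2 0.94 ± 0.12, adjusted p = 0.00155). Gclc, the catalytic subunit of glutathione synthesis, rose by a log2 difference of 0.58 ± 0.11, as did the glutathione transferase genes Gstp1 (0.57 ± 0.11) and Gstm3 (0.58 ± 0.14). The second probe set of Gstm3 did not pass (adjusted p = 0.223). The list lay higher in camera (adjusted p = 0.00029), not with an estimated correlation (adjusted p = 0.339). Limma called no gene among 14 antioxidant enzymes (3 at an unadjusted p under 0.05; 2 higher adjusted over the list alone; list adjusted p = 0.788). Calls of Gclc ended without KO903 or KO905 (adjusted p up to 0.073), of Gstp1 without KO904 or WT6 (up to 0.0714) and of Gstm3 without KO904, KO905, WT4 or WT6 (up to 0.176).

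The endoplasmic reticulum stress list lay lower (camera adjusted p = 0.00497; adjusted p = 0.339 with an estimated correlation), and 3 of its 24 tested genes fell (5 adjusted over the list alone). Dnajb9 fell from 2014 ± 244 to 1196 ± 40.2 (SD, n = 3 each; log2 -0.74 ± 0.12, adjusted p = 0.00672), the chaperone gene Hspa5 by 0.72 and Herpud1 by 0.67 on the log2 scale. Among 24 heat shock and cytosolic chaperone genes limma called none, also when adjusted over the list alone (2 at an unadjusted p under 0.05; list adjusted p = 0.373; median 0.01, from -0.05 without KO903 to 0.05 without KO904, and -0.02 after centring or quantile normalization; mean -0.04). In the acute phase list, which includes Mt2, the lipopolysaccharide binding protein gene Lbp and Serpina3n also rose, by log2 differences of 0.46 ± 0.10 and 0.42 ± 0.10, while the other 23 of 26 genes did not pass. Adjusted over the list alone the same 3 were higher, and the list was not shifted (adjusted p = 0.714; median -0.04, above 0 with the mean over probe sets; mean 0.03). Leaving out 1 library ended the calls of Herpud1 (KO903, KO904 or WT4, adjusted p up to 0.0805), of Hspa5 (KO904, KO905, WT4 or WT6, up to 0.128), and of Lbp and Serpina3n (each of the 6, up to 0.123 and 0.164).

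Cytochrome P450 and conjugation genes moved in both directions: 2 of 24 rose and 3 fell (4 higher and 3 lower adjusted over the list alone). Besides Cyp2c37 and Cyp2c39, the flavin monooxygenase gene Fmo5 fell from 6284 ± 526 to 4048 ± 737 (SD, n = 3 each; log2 -0.65 ± 0.13, adjusted p = 0.024) and Cyp2f2 from 11771 ± 521 to 9079 ± 128 (SD, n = 3 each; log2 -0.37 ± 0.08, adjusted p = 0.0332). The list did not lie apart from other genes in camera (adjusted p = 0.27). Fry, which makes no such comparison, gave an adjusted p of 0.00974 for a net fall. The median log2 difference was only -0.05 and the mean -0.02, with 9 of 24 genes above 0. How far the result of fry rests on Cyp2c37 was not tested. Of 6 tested genes of male-predominant expression, Cyp7b1 and Cyp2d9 rose (3 adjusted over the list alone). Cyp2d9 went from 1911 ± 427 to 3846 ± 428 (SD, n = 3 each; log2 1.02 ± 0.16, adjusted p = 0.00625). Camera placed this list higher (adjusted p = 0.00531), not with an estimated correlation (adjusted p = 0.339). The labels give no sex, and a difference in sex between the groups was not tested, for Cyp7b1 as for the other genes. Among 9 genes of female-predominant expression, Prom1 rose (log2 1.12 ± 0.19, adjusted p = 0.00828) and the thioesterase gene Acot3 fell (log2 -1.09 ± 0.27, adjusted p = 0.0453), with 2 higher and 3 lower adjusted over the list alone and no shift of the list (adjusted p = 0.63). The calls of Fmo5 (KO903, KO904 or WT6, adjusted p up to 0.0799), Cyp2f2 (each of the 6 libraries, up to 0.112) and Acot3 (each except WT5, up to 0.156) ended with 1 library left out.

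Few genes of central metabolism passed the threshold. In glucose metabolism 2 of 20 genes fell (3 adjusted over the list alone; list adjusted p = 0.101): the glucose-6-phosphate transporter gene Slc37a4 (log2 -0.53 ± 0.12, adjusted p = 0.0338) and the glucose transporter gene Slc2a2 (log2 -0.38 ± 0.09, adjusted p = 0.0471). Among 26 genes of the urea cycle and amino acid catabolism, Cbs and Hal rose (log2 0.46 ± 0.10 and 0.56 ± 0.13) and Glul and Asl fell (log2 -0.40 ± 0.09 and -0.67 ± 0.16), with 2 higher and 3 lower adjusted over the list alone. Second probe sets of Cbs and Glul did not pass (adjusted p = 0.124 and 0.63). That list was not shifted (adjusted p = 0.189) except without WT4 (adjusted p = 0.0119). Of 49 oxidative phosphorylation genes only the complex I gene Ndufa6 passed (log2 -0.41 ± 0.10, adjusted p = 0.043; none adjusted over the list alone; list adjusted p = 0.69), and of 24 ribosomal protein genes limma called none, also when adjusted over the list alone (2 at an unadjusted p under 0.05; list adjusted p = 0.796). All 7 of these single-gene calls ended with 1 library left out, for each of the 6 libraries with Slc2a2, Glul and Ndufa6, for 5 with Slc37a4 (not WT4), Cbs (not WT5) and Asl (not WT6), and for KO903, KO904, KO905 or WT4 with Hal. Their adjusted p then reached 0.12 to 0.172.

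Clock genes lay lower as a list (camera adjusted p = 0.00531; adjusted p = 0.339 with an estimated correlation), with a median log2 difference of -0.53 that was -0.22 without KO903 and -0.25 without WT6. Dbp and Tef, output transcription factors of the clock, were called among 11 tested genes, with 2 higher and 6 lower adjusted over the list alone. Dbp went from 1515 ± 247 to 535 ± 156 (SD, n = 3 each; log2 -1.50 ± 0.19, adjusted p = 0.00162). Tef fell by 0.67 ± 0.13 (log2 -0.67, adjusted p = 0.0176), a call that ended without KO903, KO905, WT4 or WT6 (adjusted p up to 0.0787). The mRNA splicing factor list also lay lower (camera adjusted p = 0.00531; adjusted p = 0.339 with an estimated correlation), although limma called none of its 30 genes, also when adjusted over the list alone (3 at an unadjusted p under 0.05). Tra2b and Sfpq had the smallest p in it, with log2 differences of -0.41 ± 0.13 and -0.50 ± 0.18 (adjusted p = 0.112 and 0.166).

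Among immune genes, the immunoproteasome subunits Psmb8 and Psmb9 rose, with log2 differences of 0.98 ± 0.15 and 0.75 ± 0.13 (adjusted p = 0.00545 and 0.00952). They were the calls among 16 interferon-stimulated genes (3 adjusted over the list alone), a list that lay higher in camera (adjusted p = 0.0102; adjusted p = 0.431 with an estimated correlation). Markers of Kupffer cells and macrophages lay higher as a list (camera adjusted p = 0.00531; adjusted p = 0.521 with an estimated correlation), with a median log2 difference of 0.32 and no call by limma among 13 genes (5 at an unadjusted p under 0.05; 1 higher adjusted over the list alone). In it Lyz2 and Cd5l had log2 differences of 0.73 ± 0.20 and 0.72 ± 0.24 (adjusted p = 0.0674 and 0.128). Their adjusted p ran from 0.0146 and 0.0315 without WT4 to 0.215 and 0.355 without KO903, and the log2 difference of Cd5l was 0.99 without WT4 and 0.47 without WT5. The B and plasma cell list, which holds MHC class II genes, lay higher too (camera adjusted p = 0.00863; adjusted p = 0.422 with an estimated correlation). H2-Aa rose in it (log2 0.68 ± 0.16, adjusted p = 0.043), 1 of 6 (3 adjusted over the list alone), with its second probe set not passing (adjusted p = 0.265), and Cd74 had a log2 difference of 0.44 ± 0.15 (adjusted p = 0.138). Limma called no gene among 10 NF-kappaB and inflammatory cytokine genes, also when adjusted over the list alone (0 at an unadjusted p under 0.05; list adjusted p = 0.845). Without KO903 the interferon list and the macrophage list were not called (adjusted p = 0.0532 and 0.0651), nor without WT5 (0.107 and 0.101), when the B and plasma cell list was not called either (0.0561). The call of Psmb9 ended without KO903 (adjusted p = 0.0503) and that of H2-Aa without any 1 library except KO904 (up to 0.128).

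Markers of other cell types were mostly not called or too few to test as lists. Limma called none of 12 hepatocyte markers, also when adjusted over the list alone (1 at an unadjusted p under 0.05), and their median log2 difference was -0.05 (list adjusted p = 0.107). That list passed, lower, without KO903 (adjusted p = 0.0485) or WT4 (0.0119) and after quantile normalization (0.0439), and its median was above 0 without KO905 (0.02; adjusted p = 0.482) or WT5 (0.003; adjusted p = 0.452). Sinusoidal and vascular endothelium had a median of 0.14 with no call by limma among 12 genes (6 at an unadjusted p under 0.05; 2 higher adjusted over the list alone; list adjusted p = 0.0665), and passed without KO904 (median 0.26, adjusted p = 0.0145) or WT6 (0.28, 0.0301) and at a minimum signal of 200 (0.34, 0.00959). Of 8 markers of stellate cells and fibroblasts the pericyte gene Rgs5 rose (log2 0.71 ± 0.15, adjusted p = 0.0251; 1 adjusted over the list alone; list adjusted p = 0.845), while its other 3 probe sets did not pass, and without KO903, KO904 or WT6 the call ended (adjusted p up to 0.11). In lists with fewer than 4 tested genes, which were not run as lists, the heme synthesis gene Alas2 rose from 398 ± 20.3 to 814 ± 91.8 (SD, n = 3 each; adjusted p = 0.00183), 1 of 3 erythroid markers (2 adjusted over the list alone), and the elastase gene Cela1 rose (log2 0.77 ± 0.14, adjusted p = 0.0106), 1 of 3 pancreas markers (1 adjusted over the list alone). The call of Cela1 ended without KO904 or KO905 (adjusted p up to 0.0604). Limma called neither of 2 cholangiocyte markers (both higher adjusted over the list alone and at an unadjusted p under 0.05). Limma called no marker, with either adjustment or at an unadjusted p under 0.05, among 2 of neutrophils, 2 of adipose tissue and 1 of T and NK cells, and no marker of skeletal muscle was tested.

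**Figure D3:**
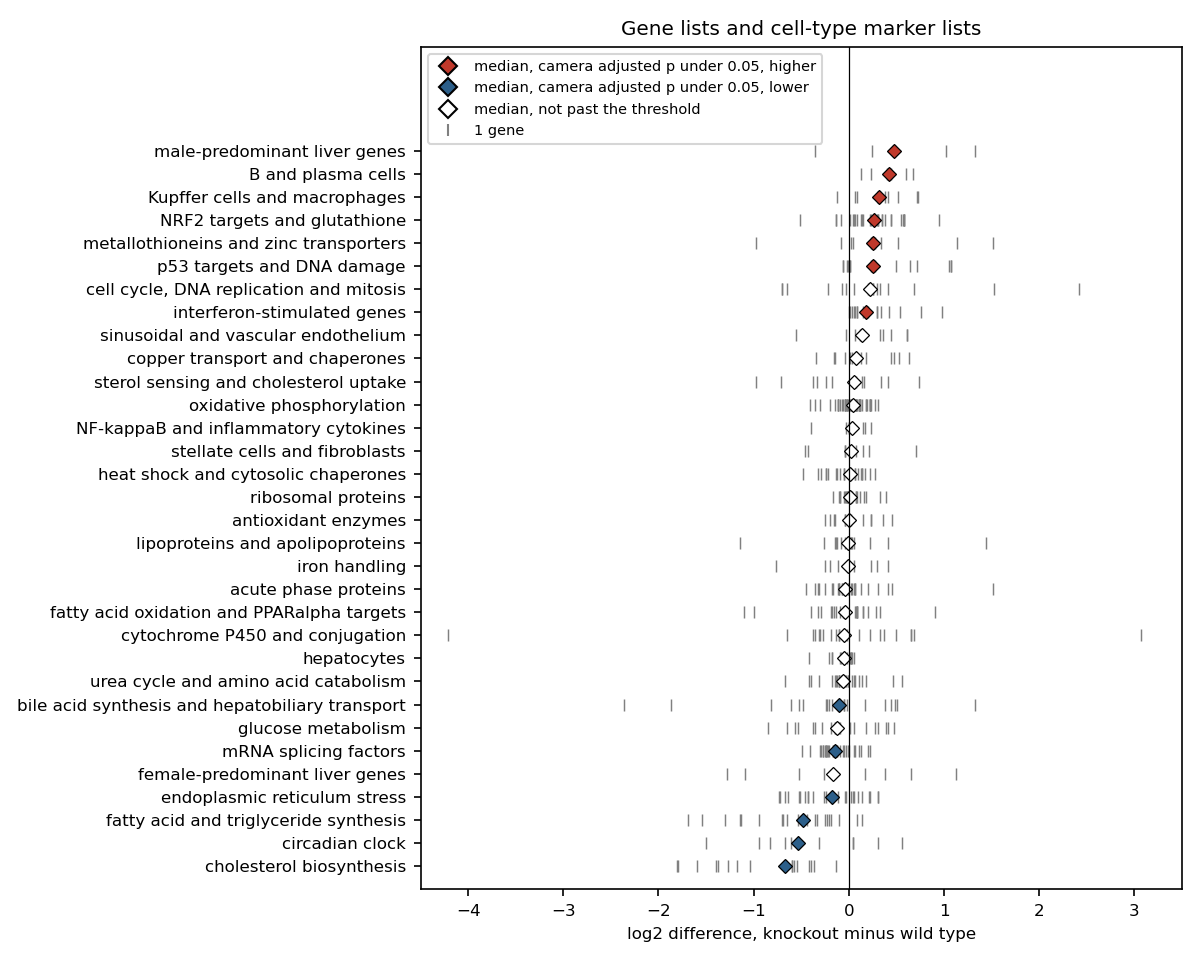
Log2 differences between knockout and wild type for each tested gene (tick) of the 32 lists that were run, with the list median (diamond; filled where camera's adjusted p is under 0.05). Of these lists 13 passed with the preset correlation, 7 higher and 6 lower, and none with an estimated correlation.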

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

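All tests in this part except the fit with no filter on signal were chosen after the results were seen. Probe sets with a mean signal under 100 were outside the main comparison. With no filter on signal, limma called 3 of these 1158 probe sets higher in the knockout (Pkhd1, another Smc4 probe set and Pdk4, chosen after their values were seen, as were the next ones), with knockout means of 115, 100 and 115 against 36.2, 40.8 and 51.6 in wild type, and 5 lower (Mme, Ppargc1a, Macir and 2 with no single symbol). At an unadjusted p under 0.05 there were 91. They are set apart here as a signal in data that the comparisons of the report leave out.

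The real split of the 6 samples called 440 probe sets, 123 of them changed at least 2-fold, and 13 lists. Each of the other 9 of the 10 splits into 3 against 3 called 0 probe sets in limma (238 to 553 at an unadjusted p under 0.05, against 1900 in the real split), none of them changed at least 2-fold, and the highest count of lists among them was 8. The real split alone (1 of 10) reached its value for each of these results, and 10 splits are too few for a share under 0.05. Every other split puts knockout and wild-type samples on both sides, so any difference between the groups adds to the spread there. Counts of 0 in those splits therefore say nothing about the cause of the difference.

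The 38 tested lipid synthesis genes of both lists had a median log2 difference of -0.62, with 36 below 0. Their fall might come from how the arrays were scaled or from a bias that depends on the signal. Against that, the lowest median of 10000 random lists of the same size matched on mean signal was -0.14. A smaller share of hepatocytes in the knockout pieces would lower hepatocyte markers by about as much, but the lowest of 12 such markers was Tat at -0.42 and their median was -0.05. Longer fasting of the knockout mice stays open: 12 tested genes that fasting raises had a median of -0.18, though 2 were above 0 and the only one called, Vnn1, was higher; they lay below other genes in camera (p = 0.00593) but not with an estimated correlation (p = 0.0875). Lpin1, which fasting also raises, was left out of those 12 because it is among the synthesis genes. It fell by a log2 difference of -1.54 ± 0.15 (limma adjusted p = 0.000332). Loss of Atp7b is the biological explanation the design offers. It was not tested apart from feeding or time of day, which the labels do not give.

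The lower clock output genes, Dbp and Tef, could reflect another time of day at sampling. Only 2 clock genes of opposite phase were tested, Clock and Nfil3, with a median log2 difference of 0.30, too few to decide. Sampling time and genotype therefore cannot be told apart for Dbp and Tef. The labels give no sampling time for any sample, so the same limit holds for any other called gene that varies over the day. Less glucocorticoid signal at sampling is also open: 15 glucocorticoid-induced genes outside the clock list had a median of -0.12, lower than other genes in camera (p = 0.0274) but not with an estimated correlation (p = 0.23).

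Some of the 87 genes changed at least 2-fold, such as Cyp2c37 and Cyp2c39, might differ through the strain background rather than through the loss of Atp7b, which stays open. Across the 48 genes with other tested probe sets, the values argue against variants that touch 1 probe set as the whole cause. Of 73 such other probe sets, 67 had the same sign (lower 95% Clopper-Pearson limit 83%). Of the 45 that were not themselves called at 2-fold, 40 did (limit 75.9%). Only 42 of the 73 were called with the same sign. An uncalled one does not exclude a variant for its own gene, since sign alone does not show a change. Cnn3 and Riok3 each had another called probe set of opposite sign, and whether probe sets of a gene share probes was not examined. For the 39 genes with no other tested probe set, Cyp2c37 and Cyp2c39 among them, a variant and a change in transcript level cannot be told apart, since a second probe set is needed. A segment linked to Atp7b does not account for the group, as 1 of the 87 genes (Lpl) lay among the 133 tested genes up to 100 places away. Other segments stay open: called genes were neighbours in 15 pairs, 3 of them within the Cyp2c cluster, against a median of 10 and a central 95% of 5 to 16 over 10000 random draws. Further pairs were of related genes too: Mt1 with Mt2, Gstp1 with Gstp3, Slc22a27 with Slc22a29, and Hsd3b2 with Hsd3b3. Random draws do not allow for such families, so the pairs say little about segments.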

How the results depend on the processing

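No alternative in this part was chosen after the results were seen. The count of 440 called probe sets was 175 to 475 with 1 sample left out and 786 at an adjusted p under 0.10; in the other alternatives it was 313 (no trend) to 550 (array weights). The count fell without each sample except WT5 (475); the cause was not tested. The count changed at least 2-fold (123) was 97 (pseudocount 64) to 146 (without WT5), and with 1 sample left out 101 to 146. Atp7b stayed uncalled throughout, between -0.34 and -0.16 on the log2 scale. Of 13 called lists, an estimated correlation left 0 (the cause was not tested). The estimated values were 0.552 for cholesterol biosynthesis and 0.418 for fatty acid and triglyceride synthesis, against the preset 0.01. They were -0.061 for metallothioneins and zinc transporters and -0.17 for male-predominant genes, whose calls ended too. Fry, which compares a list with no other genes, called 4, 2 of them among the 13. Other alternatives gave 9 to 15. Of 71 called named genes, 46 stayed called in every alternative other than a left-out sample and 39 without each sample in turn, and none changed sign. Robust eBayes ended the calls of Cyp2c39 (adjusted p = 0.196), Sqle (0.0618), Fabp5 (0.0555) and Acot3 (0.0646); quantile normalization those of Gadd45g (0.0638) and Slc2a2 (0.0505); median centring those of Gadd45g (0.0581), Gstm3 (0.0551) and Serpina3n (0.0635); and the mean over probe sets those of Gstm3 (0.097), Glul (0.164), H2-Aa (0.0956) and Rgs5 (0.0574). Without the trend 21 calls ended, those of Atox1, Srebf1, Slc10a1, Gadd45g, Gstp1, Gstm3, Herpud1, Hspa5, Lbp, Serpina3n, Fmo5, Cyp2f2, Acot3, Slc37a4, Slc2a2, Cbs, Hal, Glul, Asl, Ndufa6 and H2-Aa; the cause was not tested. No paired analysis was possible because the groups share no sample number. Low signals limit what was measured: 1158 probe sets had a mean under 100.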

Other observations

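The genes and families in this part, and their tests, were chosen after the values were seen. Beyond the genes named by rule, 4 more cytochrome P450 genes of the Cyp2c family fell: Cyp2c50 from 11654 to 4127 (log2 -1.49 ± 0.12, adjusted p = 6.61e-05), Cyp2c68 from 14509 to 6982 (log2 -1.07 ± 0.14), Cyp2c54 from 7258 to 4229 (log2 -0.77 ± 0.13) and Cyp2c55 from 360 to 196 (log2 -0.82 ± 0.15, adjusted p = 0.0145). Cyp2c39 of the same family rose, and tested members that were not called were not counted. Whether probes are shared among these related genes was not examined, and the family was not tested as a list. The tight junction genes Cldn1 and Ocln rose (log2 1.10 ± 0.16 for each, adjusted p = 0.00427 and 0.00432), and the gap junction gene Gjb2 fell (log2 -0.73 ± 0.10, adjusted p = 0.00258). The organic anion transporter gene Slc22a7 rose from 306 to 715 (log2 1.18 ± 0.15, adjusted p = 0.00155) and the deiodinase gene Dio1 from 394 to 887 (log2 1.11 ± 0.23, adjusted p = 0.024). Alas1, the first enzyme of heme synthesis in liver, fell from 6536 to 3069 (log2 -1.10 ± 0.17, adjusted p = 0.00552), and Nampt, of NAD synthesis, from 876 to 409 (log2 -1.08 ± 0.15, adjusted p = 0.00267).

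Single genes of the constitutive proteasome family, taken by gene name (Psma to Psmd), rose. Of 34 tested, 7 were called higher, Psma1, Psmb4, Psmb7, Psmc2, Psmd11, Psma7 and Psmc6, and none lower, and 31 had log2 differences above 0. A hypothesis is that the family may rise as a whole. The 27 members that were not called had a median log2 difference of 0.21, with 24 above 0. They lay higher than other genes in camera (p = 2.28e-05 with the preset correlation and p = 0.0372 with an estimated one). That test leaves out the subunits that raised the question, but its genes were measured in the same 6 samples, so it is not independent of them. The whole family, with the subunits that raised the question, had a median of 0.24 (camera p of limma 2.64e-09 and 0.02), and of 0.26 after quantile normalization and 0.21 after median centring.

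Of 22 tested kinetochore, checkpoint and condensin genes 9 were called higher, among them Trip13 (log2 1.51 ± 0.24, adjusted p = 0.00734), Ncaph, Zwint, Dsn1 and Mad2l2 besides Mad2l1, Cenpq, Pttg1 and Smc4. The whole family, put together after several of these were seen among the largest increases, had a median of 0.44 (camera in limma, p of 1.56e-07, and 0.0088 with an estimated correlation), which tests it on the genes that prompted it. The hypothesis that the whole family may rise stays open, since leaving out the called members takes away part of any rise and the other 13 cannot decide it. These had a median log2 difference of 0.019, with 7 above 0 (camera in limma, p of 0.587), and of -0.04 after quantile normalization and -0.01 after median centring.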
